A study of Mus musculus with 6 samples.

How the data were processed

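Single-cell RNA sequencing was done on mouse bone-marrow-derived macrophages (BMDMs), cells grown out of bone marrow in culture. Per the labels and the series design text, the cells were treated for 48 h with PBS, the control, or with MATAC at 100 nM. The series title concerns chimaeras that target extracellular proteins for degradation. Each group had 3 libraries, and 1 library was 1 sample throughout. The labels do not say whether the 3 libraries of a group came from separate mice or separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

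Per the labels' extraction protocol, libraries were made with the SeekOne DD 3′ droplet kit and sequenced on a GeneMind SURFSeq instrument. Per the series design text, the authors made gene expression matrices with SeekSoul tools 1.2.1 and analysed them in Seurat 4.4, and the submitters' processing notes name mm10 as the genome build. Aligner settings and the annotation used for counting are not given in the sources used here. The deposited matrices hold raw UMI counts, whole numbers per gene and cell barcode, for 32285 genes. Per the series design text, the authors removed cells with under 300 genes or over 10% mitochondrial reads, removed doublets with DoubletFinder, and named macrophage subtypes with SingleR and marker genes. The deposited counts came before those steps, since barcodes under 300 genes and over 10% mitochondrial UMIs were still present, and the authors' cell labels were not used here.

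Barcodes with 300 or more genes and at most 10% mitochondrial UMIs were kept. Doublets were called in each library by the share of simulated doublets among a cell's neighbours, at a rate of 0.8% per 1000 barcodes, with code written for this purpose in place of DoubletFinder. When known doublets were added to each library, 30.9 to 39.6% of them were called, against 5.09 to 7.84% of the other barcodes, so many doublets stay among the retained cells. Calls made up 6.45 to 9.51% of the barcodes that passed the filters. Retained cells numbered 29135 in PBS and 24140 in MATAC libraries, with 84.2 to 103 M UMIs (M, mega) per library.

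Expression levels are CPM, counts scaled to a common library total in the usual way. For clustering, retained cells were scaled to a common total, log-transformed and grouped on 2000 variable genes chosen within libraries, 30 principal components, 20 neighbours and Leiden resolution 0.8, with no batch correction (seed 1). This gave 27 clusters. A cluster was named for a class when at least 3 of the class's fixed markers had a log2 fold of 0.5 or more over other cells (10 CPM added) at 10 CPM or more, and the markers' mean log2 fold was 0.25 or more. The last limit was set after the clusters were seen, and it left 1 cluster without a name that would otherwise have been called lipid-associated: that cluster held 2.85 ± 0.275% of PBS and 3.12 ± 0.652% of MATAC cells (SD, n = 3 each). Clusters led by another fixed list, and clusters of very low UMI number with none of the class's markers among their leading genes, stayed unnamed. The suffix -like marks these classes as rebuilt here from 16 marker sets of 97 genes, and their bounds need not be those of the study.

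UMI counts were summed over the cells of each library and compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, treatment the only term, two-sided), for all retained cells and within each macrophage class of 50 or more cells in every library. Benjamini-Hochberg adjusted p-values under 0.05 were called. Errors after log2 fold changes are standard errors from these fits, and errors after CPM or percentages are SD over 3 libraries. Of 42 fixed gene lists, 41 had members enough to test, and 751 of their 763 genes were measured. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Shares of cells were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 is 0.1, and cell numbers per cluster by edgeR with the library total as offset. For the study's markers, each cell was thinned to 2043 UMIs, the 20th percentile, and cells below that were left out. The classes' own response was also set side by side in a single edgeR fit with library, class and the class by treatment interaction, a test added after the first results were seen.

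The gene lists, marker sets, main tests and the rule for named genes were chosen before the data were examined. Tests and limits added later are marked as such, here or in the closing sections. The rule took the 9 subtype markers of the study, up to 10 called genes in each direction, up to 4 called members of each list past its test, and, where fewer than 10 genes passed, the 10 of smallest p. It named 19 genes in the comparison of all cells. Loci were looked up by gene identifier in GENCODE M21 on GRCm38, the assembly also called mm10, and 26 of 26 identifiers looked up were matched.

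The fits were tested on simulated data with the depth of these libraries. In 15851 simulated genes edgeR recovered 44 of 50 genes changed 1.2-fold and 50 of 50 changed 1.5-fold, with 27 false calls. In all 200 genes were changed, 50 each at 1.2-, 1.5-, 2- and 3-fold. So many changed genes ease the adjusted threshold, so the recovery at 1.2-fold does not hold where few genes change strongly. Camera called the 1 list to which a log2 change of 0.3 had been added and no other of the 41 lists. Genes were simulated as independent of each other, so this says nothing of false calls where list members vary together. Estimated correlations in the real lists reached 0.917 (G2 and M phase). EdgeR on cell numbers called the 1 cluster raised 1.5-fold (adjusted p = 0.00189) and 0 others. The interaction fit recovered 3 of 50 genes changed 1.2-fold and 34 of 50 changed 1.5-fold, with 3 false calls in 12641 genes. That simulation also changed 200 genes and gave every gene the same fixed dispersion, so the same limit applies.

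Alternatives were DESeq2 1.42.0, its size factors within edgeR, library totals as scaling, no filter on low counts, stricter or no barcode filters, doublets kept, thinned cells, other clusterings, a naming of single cells by marker score, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and leidenalg 0.10.2 was used for counts and clustering, and matplotlib 3.10.9 for the figures.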

Results

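RNA of single BMDMs was counted after 48 h with PBS (n = 3 libraries) or with 100 nM MATAC (n = 3 libraries). The PBS libraries held 11692, 14291 and 12121 barcodes with 112592345, 125182942 and 115266894 UMIs, and the MATAC libraries 10227, 11497 and 10818 barcodes with 103604481, 114621212 and 98150503 UMIs. After filtering, 9712 ± 904 PBS and 8047 ± 585 MATAC cells per library were retained (SD, n = 3 each). Retained cells had a median of 8276 ± 746 UMIs in PBS and 8911 ± 423 in MATAC libraries, and the groups overlapped (exact permutation p = 0.3).

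The series design text asks whether MATAC shifts macrophage subtypes: unpolarized M0 cells, activated cells, lipid-associated macrophages (LAM), and M2a and M2c cells, both forms of alternative activation. LAM-like cells, the class marked by the lipid receptor gene Trem2 and by Gpnmb, made up 20.7 ± 1.23% of cells in PBS and 18.2 ± 0.161% in MATAC libraries (SD, n = 3 each), lower in each MATAC library than in each PBS library. Neutrophil-like cells, marked by granule and calprotectin genes such as S100a8, made up 3.42 ± 0.0535% and 4.07 ± 0.213%, higher in each MATAC library than in each PBS library. M2c-like cells, the class of Mertk, a receptor for the uptake of dying cells, made up 24.1 ± 3.18% and 25.8 ± 1.22%. Cycling cells, marked by Mki67, made up 3.79 ± 0.561% and 4.34 ± 0.566%, and monocyte-like cells, marked by Ly6c2 and Ccr2, 4.06 ± 0.0751% and 4.04 ± 0.293%.

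None of these shares passed a test. The exact permutation p was 0.1, the smallest possible, for LAM-like (difference of -2.50 percentage points) and neutrophil-like cells (0.652 points), with a Benjamini-Hochberg value of 0.55 over 11 classes. It was 0.6 for M2c-like cells (1.68 points), 0.4 for cycling and 1 for monocyte-like cells. With edgeR on cell numbers per class, a test added after the data were seen, 0 of 11 classes were called. Unadjusted p was under 0.05 for 2 of them: the log2 ratio was 0.25 ± 0.10 for neutrophil-like cells and -0.19 ± 0.09 for LAM-like cells (adjusted p = 0.221 for both). Without PBS replicate 2, the library with the lowest M2c-like share at 20.4%, edgeR called 3 classes: LAM-like (-0.23, adjusted p = 0.00075), cycling (0.32, adjusted p = 0.00239) and neutrophil-like (0.26, adjusted p = 0.0135). The groups overlapped for LAM-like cells in each of 5 other clusterings, where the difference was -0.843 points at Leiden resolution 1.5, -0.961 with scaling within libraries, -1.54 with doublets kept, -1.70 without the 500 genes of smallest p and -1.74 at resolution 0.4. At resolution 1.5 a cluster of 2961 cells with Fabp4 and Fabp5 among its leading genes stayed unnamed, and so outside the LAM-like share. Its log2 ratio was -0.35 (adjusted p = 0.534 in edgeR). By marker score of single cells the LAM-like difference was -3.70 points, without overlap. The neutrophil-like difference fell to 0.117 points with scaling within libraries and to 0.142 points without the 500 genes, again with overlap, and to 0.251 points at resolution 1.5, but was 0.713 points at resolution 0.4 and 1.32 points by marker score. At resolution 1.5 and without the 500 genes, a cluster led by Cxcr2 and the interleukin gene Il1b was named inflammatory.

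**Figure D1:**
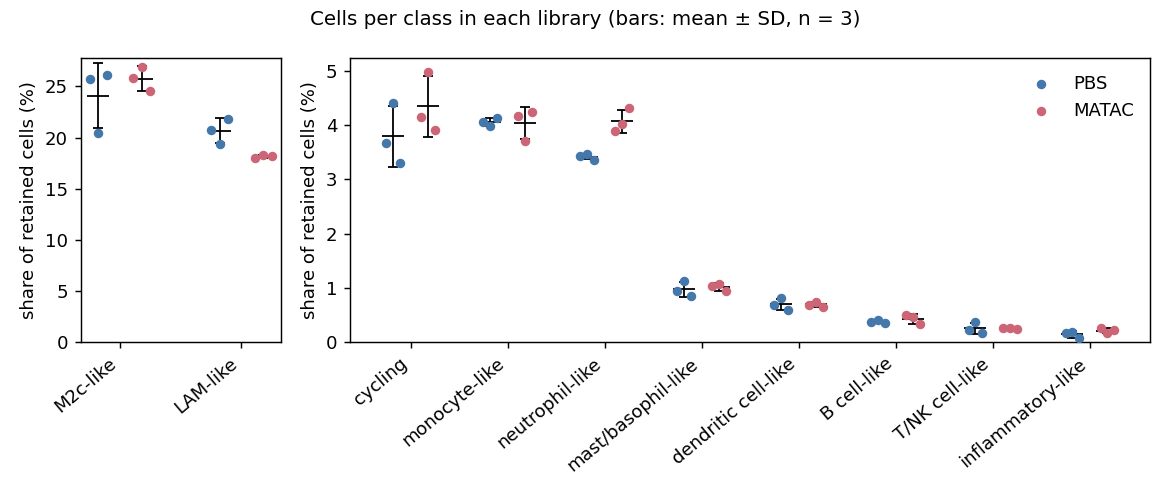
Share of retained cells (%) in each class, 1 point per library, with the mean and SD of 3 libraries as bars. For LAM-like cells the lowest PBS library, at 19.4%, lies above the highest MATAC library, at 18.3%.

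Smaller groups of cells stood near 1% or below in both groups. Mast or basophil-like cells made up 0.970 ± 0.143% and 1.01 ± 0.0684%, dendritic-cell-like cells 0.694 ± 0.108% and 0.694 ± 0.0511%, B-cell-like cells 0.373 ± 0.0270% and 0.431 ± 0.0905%, and T or NK-cell-like cells 0.255 ± 0.0973% and 0.257 ± 0.0139%. Inflammatory-like cells, the other part of the study's activated class, were 95 cells of low UMI number, 0.149 ± 0.0640% and 0.214 ± 0.0519%. By marker score of single cells the inflammatory share was 7.90 and 7.17%, lower in each MATAC library, and at resolution 1.5 it was 3.51 and 3.98%, higher in each. At that resolution 1405 of the 1982 cells so named were the cluster led by Il1b, an inflammatory marker here, and Cxcr2, a gene of neutrophils. This value is thus not one of macrophages alone. No cluster met the rule for M0 or M2a at the resolution used. Clusters named M0 held 5.02 and 5.00% at resolution 1.5 (274 of these 2662 cells were a cluster with the LAM markers Spp1 and Lpl among its leading genes) and 0.474 and 0.476% with scaling within libraries, while marker scores gave 12.8 and 14.3% for M0 and 3.12 and 3.04% for M2a, all with overlapping groups. At the resolution used, 41.5 ± 3.40% of PBS and 41.0 ± 1.53% of MATAC cells lay in clusters without a class name. Among 27 clusters edgeR called 0, with 4 at unadjusted p under 0.05 and a lowest adjusted p of 0.232. The largest ratio of these was in a cluster of 176 cells led by the fatty acid binding protein genes Fabp4 and Fabp5, 0.430 ± 0.172% of PBS and 0.200 ± 0.0277% of MATAC cells (log2 ratio -1.13 ± 0.34). Small clusters with Fabp4 among their leading genes in other clusterings did not show this, at -0.03 (92 cells, resolution 1.5) and -0.13 (100 cells, without the 500 genes). Larger clusters with Fabp4 among their leading genes were at -0.35 (2961 cells) and -0.06 (6097 cells) at resolution 1.5. They were at -0.10 (13358 cells) at resolution 0.4 and -0.18 (7348 cells) without the 500 genes, and none was called. Without PBS replicate 1 the cluster of 176 cells alone was called (-1.39, adjusted p = 0.00799).

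In all retained cells the genes with the smallest p were mostly lower in MATAC libraries. Fos, an immediate early transcription factor gene (ENSMUSG00000021250, GRCm38 chromosome 12, 85473890 to 85477273), had 103 ± 3.46 CPM in PBS and 84.4 ± 2.83 CPM in MATAC libraries, a log2 fold change of -0.28 ± 0.04. Its relative Fosb went from 2.83 ± 0.177 to 1.92 ± 0.0425 CPM (-0.56 ± 0.09). The lipid-handling genes Fabp5 (chromosome 3, 10012548 to 10016607), Fabp4 (chromosome 3, 10204088 to 10208576) and Mgll, a monoacylglycerol lipase gene, had log2 fold changes of -0.27 ± 0.05, -0.29 ± 0.05 and -0.27 ± 0.04, with Fabp5 at 5451 ± 117 and 4528 ± 116 CPM. Cxcr2, a chemokine receptor gene of neutrophils, was at 16.99 ± 0.426 and 21.4 ± 1.10 CPM (0.33 ± 0.05), and among macrophage clusters alone its log2 fold change was 0.00275 (adjusted p = 0.998).

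None of the 15851 genes tested passed edgeR at this design, so these 10 genes are those of smallest p and did not pass (adjusted p = 0.279). The others among them were Npy, a neuropeptide gene (-0.20 ± 0.03), Nenf (-0.23 ± 0.04), Coa4, a cytochrome oxidase assembly gene (-0.23 ± 0.04), and Ubald1 (-0.18 ± 0.03). At unadjusted p under 0.05, 682 genes were higher and 920 lower, but 1504 higher and 328 lower when scaled by library totals alone. DESeq2 called 126 genes, 11 higher and 115 lower, with Fabp5 (adjusted p = 1.6e-09) and Fos (adjusted p = 5.8e-07) first. It gave Cxcr2, Coa4 and Fosb no adjusted p-value. Groups did not overlap for 1186 higher and 1362 lower genes, where chance gives 10% of genes. Changes were small: of 7942 genes of 10 CPM or more, 7895 (99.4%) had a 95% interval within a log2 change of 0.5 either way.

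**Figure D2:**
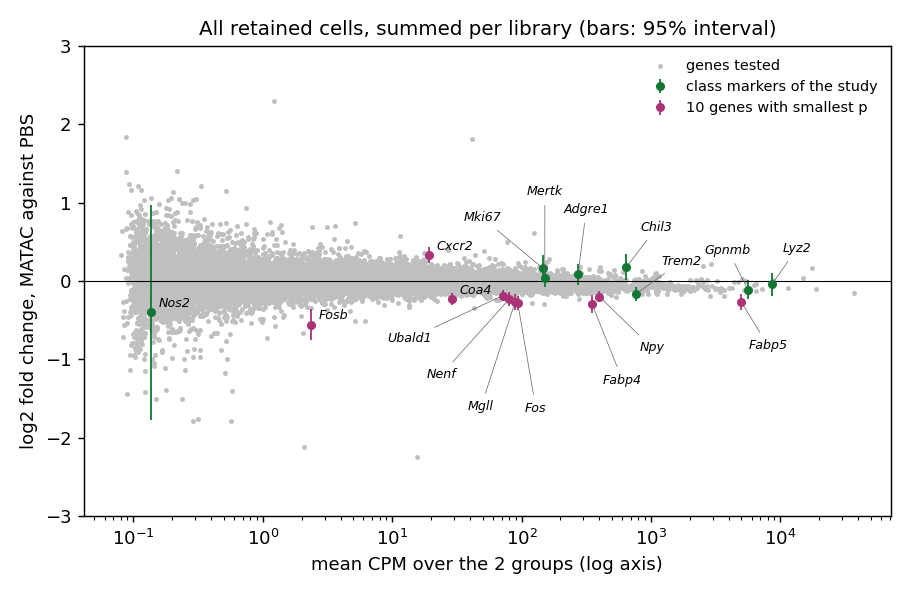
Log2 fold change of each gene, MATAC against PBS, over its mean CPM (log axis), with 95% intervals for the study's markers (green) and the 10 genes of smallest p (purple). Of these 10, Cxcr2 alone lies above 0.

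Of the 9 subtype markers of the study, Trem2 (chromosome 17, 48346401 to 48354147) was nearest to a change, at 815 ± 12.9 CPM in PBS and 730 ± 21.8 in MATAC libraries (-0.16 ± 0.04, adjusted p = 0.374 in edgeR), lower in each MATAC library. DESeq2 called it (adjusted p = 0.00299). Gpnmb, the other LAM marker, had a log2 fold change of -0.11 ± 0.05, and the M0 markers Lyz2, the lysozyme gene, and Adgre1, which encodes F4/80, -0.04 ± 0.06 and 0.08 ± 0.06. Mertk (chromosome 2, 128698956 to 128802894) was at 149 ± 8.501 and 153 ± 5.68 CPM, and its change of 0.04 ± 0.05 (adjusted p = 0.823) had a 95% interval of -0.07 to 0.14. Chil3, the chitinase-like gene used for M2a, had 0.18 ± 0.07 (adjusted p = 0.455), and the proliferation gene Mki67 0.16 ± 0.08 (0.06 in thinned cells). When 1 library was left out, Chil3 had 0.12 to 0.28, Mki67 0.08 to 0.26 and Adgre1 0.02 to 0.16. Nos2, the inducible nitric oxide synthase gene, gave 45 UMIs in PBS and 32 in MATAC libraries. Its log2 fold change of -0.40 ± 0.61 (adjusted p = 0.853 in edgeR) had a 95% interval of -1.77 to 0.98, too wide for a direction. Arg1, the arginase gene, gave 19 and 19 UMIs, too few to be tested at this depth.

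For the share of cells with a UMI, each cell was thinned to 2043 UMIs, which left out 1707 to 2334 cells per PBS library and 1511 to 1703 per MATAC library. Trem2 was seen in 67.5 ± 0.256% of PBS and 63.6 ± 1.06% of MATAC cells (n = 3 each, exact permutation p = 0.1, Benjamini-Hochberg 0.45 over 9 genes), Chil3 in 10.1 ± 0.509% and 11.1 ± 0.594% (exact p = 0.1, Benjamini-Hochberg 0.45) and Mertk in 27.2 ± 1.60% and 28.7 ± 1.47% (exact p = 0.4). Unthinned shares were 76.9 and 75.6% for Trem2, 12.8 and 14.2% for Chil3 and 53.1 and 54.9% for Mertk. B-cell-like cells, which should lack these genes, had a UMI of Trem2 in 1.89%, Chil3 in 0.472% and Mertk in 0.943% of thinned cells, at a median of 9548 UMIs per cell before thinning, against the library medians of 7416 to 9255. By class, Trem2 was seen in 83.4% of LAM-like, 73.3% of M2c-like and 3.34% of neutrophil-like cells, and Chil3 in 69.7% of monocyte-like and 1.01% of LAM-like cells. The other 6 markers had exact p-values of 0.2 to 1.

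By camera, genes of lipid-associated macrophages, of the acid pump of lysosomes and of nuclear oxidative phosphorylation were lower as groups in MATAC libraries. Genes of neutrophils, monocytes, mitosis and the interferon response were higher. Camera called 13 of 41 lists, and with an estimated correlation 0 were called. List levels per library were also taken as the mean log2 CPM of members of 10 CPM or more, scaled by library totals. Each MATAC library lay below each PBS library for lipid-associated (-0.0800) and acid pump genes (-0.0426). The groups overlapped for oxidative phosphorylation (-0.0382, exact permutation p = 0.2), interferon response (0.102, 0.2), immediate early (-0.0308, 0.3) and lysosome genes (-0.0159, 0.6). The lipid-associated list had a median log2 fold change of -0.12, with 19 of 21 members below 0 (camera adjusted p = 4.8e-09; adjusted p = 0.0925 with an estimated correlation). Adjusted over the list alone, 5 members were lower and 0 higher: Fabp4, Fabp5 and Syngr1 (adjusted p = 0.00165 each), Trem2 (0.0126) and the osteoclast and macrophage pump gene Atp6v0d2 (0.0287). Over all genes tested, 0 passed. Syngr1, at -0.22 ± 0.04, and Atp6v0d2, at -0.14 ± 0.04, fell outside the rule for named genes and were chosen after their values were seen, as were further list members beyond it. The LAM-like share, which holds cells rich in these genes, was lower in the same libraries.

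The vacuolar ATPase list, the proton pump that acidifies endosomes and lysosomes, had a median of -0.09 with 15 of 16 members below 0 (camera adjusted p = 5.1e-07; adjusted p = 0.259 with an estimated correlation). Adjusted over the list alone, Atp6v0e (-0.16 ± 0.04), Atp6v0c (-0.16 ± 0.04), Atp6v1f (-0.14 ± 0.04) and Atp6v0d2 were lower and 0 were higher. The lysosome list had a median of -0.05 with 29 of 34 members below 0 (camera adjusted p = 1.1e-05; adjusted p = 0.603 with an estimated correlation), led by Cd68 (-0.16 ± 0.04), and the endocytic machinery -0.03 with 23 of 32 below 0 (camera adjusted p = 0.0453; adjusted p = 0.603 with an estimated correlation). The endocytic call ended, and its median became 0.01, when scaled by library totals (adjusted p = 0.434). It also ended without PBS replicate 1 (0.128), PBS replicate 3 (0.284), MATAC replicate 2 (0.0975) or MATAC replicate 3 (0.101). In the lysosome and endocytic lists 0 members passed when adjusted over the list alone.

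Oxidative phosphorylation genes of the nucleus had a median of -0.08 with 28 of 30 members below 0 (camera adjusted p = 2.7e-10; adjusted p = 0.559 with an estimated correlation), for example Ndufs5 (-0.15 ± 0.04) and Cox5a (-0.12 ± 0.04). Genes of the mitochondrial genome were not called (median 0.01, adjusted p = 0.793). Cytosolic ribosomal protein genes had a median of -0.08 with 37 of 38 below 0 (camera adjusted p = 1.9e-07; adjusted p = 0.708 with an estimated correlation), and the proteasome list -0.04 with 24 of 28 below 0 (camera adjusted p = 6.0e-05; adjusted p = 0.350 with an estimated correlation). Of these lists only Psmd8 of the proteasome passed when adjusted over the list alone (-0.15 ± 0.03, adjusted p = 0.0249). Scaling by library totals moved medians upward: lipid-associated -0.08, vacuolar ATPase -0.05, oxidative phosphorylation and ribosomal -0.04 each, immediate early -0.02, lysosome and proteasome -0.01 each, interferon 0.09, G2 and M phase 0.16, monocyte 0.22, neutrophil 0.23 and B cell 0.35. Of the 13 lists only the endocytic one was then not called.

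Immediate early and heat shock genes, which respond within minutes to stimuli and stress, had a median of -0.06 with 20 of 24 members below 0 (camera adjusted p = 0.00039; adjusted p = 0.259 with an estimated correlation). Adjusted over the list alone, 3 were lower and 0 higher: Fos (adjusted p = 0.00087), Fosb (0.00141) and the zinc finger gene Egr1 (-0.33 ± 0.07, 0.0108). Of the list's 17 members of 10 CPM or more, 9 were lower and 8 higher when scaled by library totals. The labels give no times between culture and capture. Fry called 3 lists, all lower: lipid-associated (adjusted p = 0.0126), vacuolar ATPase and immediate early (0.0370 each).

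Neutrophil genes had a median of 0.19 with 15 of 15 members above 0 (camera adjusted p = 4.5e-06; adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone Cxcr2 passed (adjusted p = 0.0006), while Camp, a granule peptide gene, had 0.38 ± 0.12 and S100a8 0.21 ± 0.10. The neutrophil-like share was higher in the same libraries, and among macrophage clusters alone the list was not called (adjusted p = 0.123). Monocyte genes had a median of 0.18 with 11 of 11 above 0 (camera adjusted p = 4.5e-06; adjusted p = 0.559 with an estimated correlation), including Vcan (0.34 ± 0.10) and the chemokine receptor gene Ccr2 (0.16 ± 0.06). Genes of G2 and M phase had a median of 0.13 with 22 of 22 above 0 (camera adjusted p = 1.1e-05; adjusted p = 0.708 with an estimated correlation), and without PBS replicate 3 that call ended (adjusted p = 0.158). The shares of clusters in each library alone would give a difference in list level of 0.173 for G2 and M phase, against 0.170 measured, of 0.208 against 0.225 for neutrophil genes and of 0.116 against 0.229 for monocyte genes. In the same way it was 0.0458 against 0.102 for interferon response, -0.0241 against -0.0426 for vacuolar ATPase and -0.0375 against -0.0800 for lipid-associated genes, while for immediate early genes shares would give 0.0298 against -0.0308 measured. No single monocyte or G2 and M gene passed when adjusted over the list alone.

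The interferon response list had a median of 0.05 with 22 of 25 members above 0 (camera adjusted p = 5.4e-05; adjusted p = 0.562 with an estimated correlation). Isg15, a ubiquitin-like interferon-induced gene, passed when adjusted over the list alone (0.15 ± 0.03, adjusted p = 0.0292). B cell genes had a median of 0.31 with 9 of 9 above 0 (camera adjusted p = 0.00027; adjusted p = 0.559 with an estimated correlation), 0 of which passed when adjusted over the list alone. The immunoglobulin gene Igkc differed most between libraries, at 18.3 ± 2.31 and 63.9 ± 62.2 CPM, and among macrophage clusters alone the B cell list was not called (adjusted p = 0.568).

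Camera did not call the other 28 lists. These included the lists for inflammatory (M1) genes (median 0.04, adjusted p = 0.765), alternative activation (M2a, 0.07, 0.235), deactivation (M2c, 0.01, 0.608), efferocytosis, the uptake of dying cells (0.01, 0.823), and uptake and scavenger receptors (0.02, 0.793). Autophagy and the unfolded protein response, at medians of -0.03 and -0.02, had adjusted p-values of 0.0608 each.

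**Figure D3:**
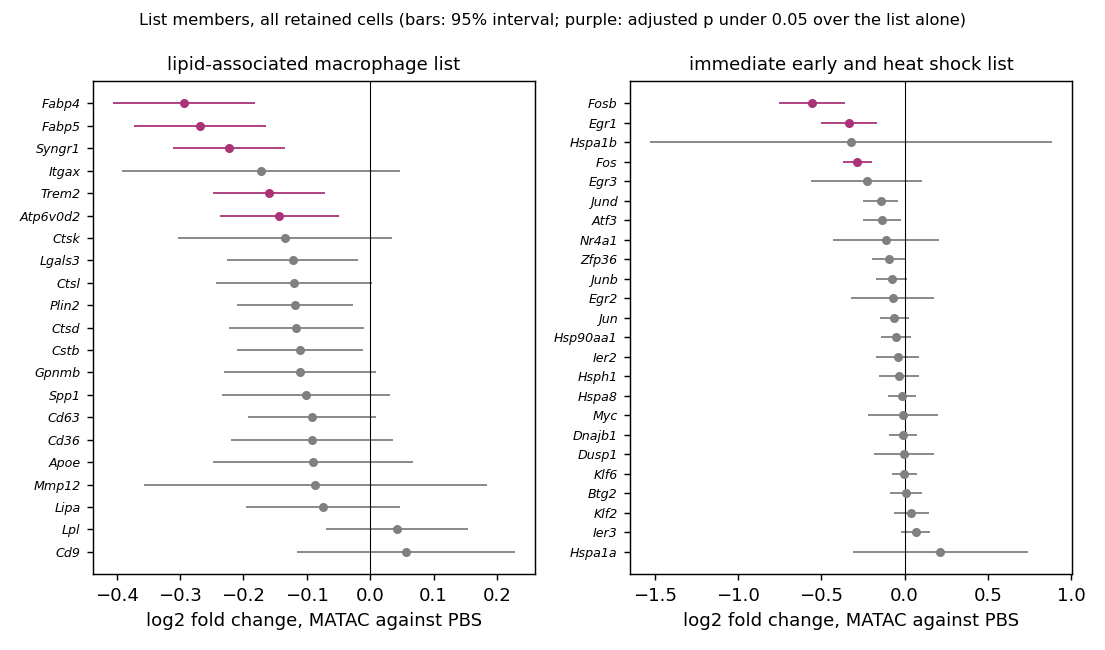
Log2 fold change, MATAC against PBS, with its 95% interval for each member of the lipid-associated (left) and the immediate early and heat shock (right) lists in all retained cells. Members with adjusted p under 0.05 over the list alone, 5 on the left and 3 on the right, are purple.

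Within classes, the shares of the classes no longer enter, but shares of the clusters that make up a class still do. In M2c-like cells Fos fell from 119 ± 8.94 CPM in PBS to 86.0 ± 6.95 CPM in MATAC libraries (-0.48 ± 0.06, adjusted p = 0.00205 in edgeR), and Ccl5, a chemokine gene that attracts T cells and monocytes (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), rose from 58.9 ± 9.10 to 89.4 ± 9.75 CPM (0.58 ± 0.09, adjusted p = 0.0247). These 2 were the only genes edgeR called among 12581 in M2c-like cells, which had 21.3 to 26.2 M UMIs per library. Both were named after their values were seen. Fos missed the threshold without MATAC replicate 3 (adjusted p = 0.0508), and Ccl5 missed it in DESeq2 (0.471) and without PBS replicate 1 (0.0532), PBS replicate 3 (0.152) or MATAC replicate 3 (0.222).

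In the other classes Fos had log2 fold changes of -0.31 ± 0.06 (LAM-like, adjusted p = 0.172), -0.24 ± 0.07 (monocyte-like, 0.725) and -0.22 ± 0.07 (cycling, 0.818), and Ccl5 of 0.16 ± 0.10 (LAM-like, 0.667), 0.86 ± 0.19 (monocyte-like, 0.473) and 0.10 (cycling, 0.984). The LAM-like Ccl5 value was 0.32 without PBS replicate 1 and 0.03 without PBS replicate 2, and the cycling value ran from -0.84 to 0.96 when 1 library was left out. Trem2 had -0.13 ± 0.05 in LAM-like and -0.12 ± 0.05 in M2c-like cells, and Fabp5 -0.19 ± 0.05, -0.16 ± 0.05 and -0.32 ± 0.07 in LAM-like, M2c-like and cycling cells, none past adjustment. Mertk in M2c-like cells had 0.10 ± 0.05 (adjusted p = 0.772). EdgeR called 0 of 12858 genes in LAM-like cells (25.6 to 34.8 M UMIs per library, 529 higher and 583 lower at unadjusted p under 0.05, 21 called by DESeq2). It called 0 of 11595 in cycling cells (6.47 to 9.35 M UMIs, 342 and 343, 3 by DESeq2). In monocyte-like cells it called 0 of 10470 (4.56 to 5.25 M UMIs, 347 and 251, 1 by DESeq2). Leaving out PBS replicate 1 gave 12 genes in LAM-like and 7 in cycling cells, and leaving out PBS replicate 2 gave 3 in monocyte-like cells.

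The study asked what marks its M2c cluster. Against other cells of the same library, M2c-like cells were rich in interferon response genes, and poor in MHC class II, M2a and cell cycle genes. Deactivation and complement genes were higher as lists too, but the class markers among them are high by the naming rule. The low lists also follow in part from that rule. It left clusters led by MHC class II genes unnamed, and clusters that scored higher for cycling or M2a could not be M2c-like. Mertk stood at 249 ± 17.4 against 119 ± 5.31 CPM in other cells (log2 difference 1.06 ± 0.10, n = 6 libraries), Stab1, a scavenger receptor gene, at a log2 difference of 1.56 ± 0.06, C1qa, a complement gene, at 1.27 ± 0.07, and the transcription factor gene Maf at 1.10 ± 0.04. These 4 are among the markers that define the class, so their direction is given by its making, and no test was done. Outside the marker set, Fcgrt, the recycling receptor of IgG and albumin, was at 1.40 ± 0.09, Cd5l at 1.05 ± 0.09 and Mrc1, the mannose receptor gene, at 1.01 ± 0.06. Mfge8, a bridging protein for dying cells, was at -1.38 ± 0.19. Other genes looked at outside the marker set differed less: Trem2 0.21 ± 0.04, Lrp1 0.18 ± 0.05, Axl 0.16 ± 0.07, Itgav 0.10 ± 0.09, Pros1 0.02 ± 0.10, Gpnmb -0.06 ± 0.08 and Cd36 -0.48 ± 0.16. Of all these only Trem2 and Gpnmb fell under the rule for named genes. Mrc1 is among the M2a markers fixed here.

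Over lists, the median log2 difference was 0.70 ± 0.04 for deactivation genes (n = 6 libraries, 13 of 17 members higher in every library and 3 lower). This list holds all the class markers, so its level is largely given by the making of the class. The median difference was 0.49 ± 0.08 for interferon response (17 of 25 higher), 0.18 ± 0.04 for lysosome (26 of 34) and 0.18 ± 0.03 for endocytic machinery (22 of 32). Lists with some class markers were complement, at 0.41 ± 0.05 (6 of 11, with C1qa, C1qb and C1qc as markers), and efferocytosis, at 0.16 ± 0.04. Of 23 efferocytosis genes 12 were higher in every library, class markers among them, and 7 lower. Below 0 were the lipid-associated list at -0.23 ± 0.07, M1 at -0.32 ± 0.06, glycolysis at -0.34 ± 0.02, M2a at -1.08 ± 0.13, MHC class II at -1.65 ± 0.12 and G2 and M phase at -3.49 ± 0.12. Other cells hold the clusters named for other classes or led by MHC class II genes, so levels below 0 for their lists are in part given by the naming.

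**Figure D4:**
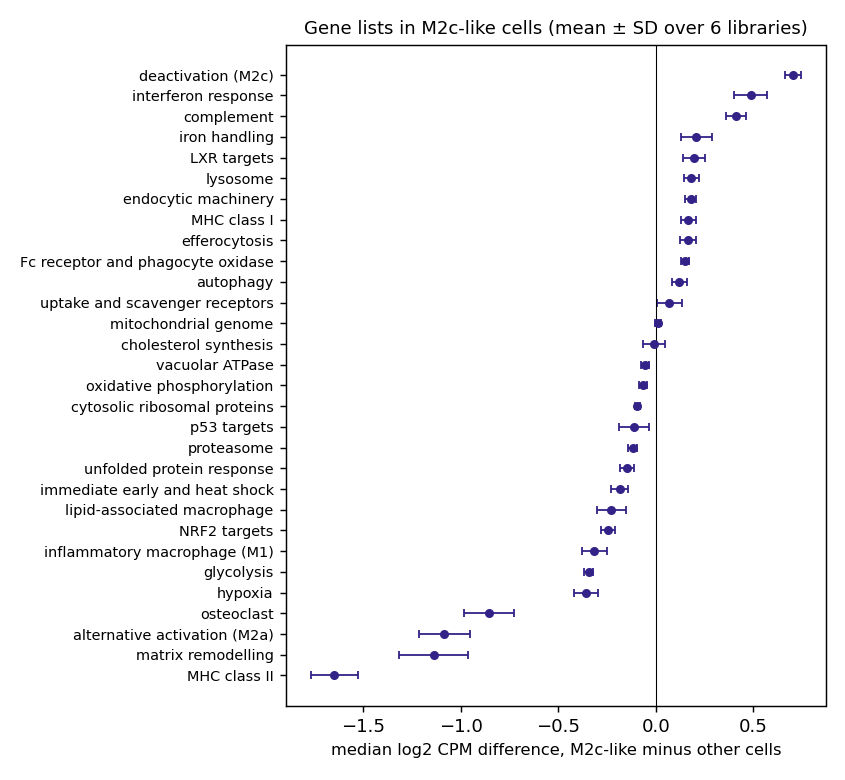
Median log2 CPM difference between M2c-like and other cells of the same library for 30 gene lists, as the mean and SD over 6 libraries. Lists of the cell cycle and of other cell types, several of them far lower, are not shown. Of the 30, deactivation genes, a list that holds all the class markers, lie highest, at 0.70, and MHC class II genes lowest, at -1.65. Clusters led by MHC class II genes were kept out of the class by the naming rule.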

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

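The class by treatment interaction, its splits and the tests of explanations for the 3 patterns weighed were chosen after the results were seen, while the splits of libraries for genes, lists, clusters and classes were chosen before.

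EdgeR called 6 of 13108 genes for a different response to MATAC in LAM-like and M2c-like cells in an interaction test (621 at unadjusted p under 0.05). Thbs1, which encodes the matrix glycoprotein thrombospondin, had a log2 fold change of 0.38 ± 0.09 in LAM-like and -0.14 ± 0.08 in M2c-like cells, a difference of -0.52 ± 0.07 (adjusted p = 0.00138). Ly6a, an interferon-inducible surface protein gene, had 0.51 ± 0.17 and -0.19 ± 0.09 (difference -0.69, adjusted p = 0.00786), and Marcksl1, a gene of an actin-binding protein, 0.31 ± 0.07 and -0.14 ± 0.06 (-0.45, adjusted p = 0.00786). Ifit3, an interferon-induced gene, had 0.21 ± 0.05 and -0.06 ± 0.05 (-0.28, adjusted p = 0.0158), and Klk1b11, a kallikrein gene, 0.27 ± 0.09 and -0.16 ± 0.08 (-0.42, adjusted p = 0.0178). Mfge8, which bridges dying cells to phagocytes, differed the other way, with -0.30 ± 0.05 in LAM-like and -0.03 ± 0.06 in M2c-like cells (0.27, adjusted p = 0.0158). In LAM-like cells, over all 6 libraries, Ly6a stood at 6.95 CPM (74.1 in M2c-like cells), Marcksl1 at 11.3 (48.3) and Thbs1 at 13.9 (52.8). Ifit3, Klk1b11 and Mfge8 stood at 38.3 CPM or more there. Monocyte and neutrophil lists were higher in LAM-like cells too (medians 0.45 and 0.30). Whether RNA of other cells gave the rises there was not tested. Thbs1 passed without each library in turn. Marcksl1 missed the threshold without PBS replicate 1 (0.0549), Ly6a without MATAC replicate 3 (0.0578), Ifit3 without PBS replicate 1 (0.125), MATAC replicate 1 (0.207) or MATAC replicate 2 (0.0896), Mfge8 without PBS replicate 2 (0.110), PBS replicate 3 (0.0828) or MATAC replicate 2 (0.305), and Klk1b11 without PBS replicate 2 (0.110), PBS replicate 3 (0.0511), MATAC replicate 1 (0.0515) or MATAC replicate 3 (0.0904). The same test did not show a difference for Fos (-0.17 ± 0.06, adjusted p = 0.808) or Ccl5 (0.42 ± 0.12, adjusted p = 0.532). Of the 10 splits of the 6 libraries, 3 called as many genes, the highest other split 7, and 10 splits cannot give a share under 0.05.

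The same holds for the other fits: 10 splits cannot give a share under 0.05. Where the true grouping called 0, every split calls as many by definition, so such counts say nothing. This holds for genes in all cells (highest other 2) and for clusters (highest other 3). It also holds for genes in LAM-like (highest other 21), cycling (highest other 12) and monocyte-like cells (highest other 14). At unadjusted p under 0.05 in all cells, the true grouping gave 1602 genes, the most of the 10 splits, and the others 366 to 990. As many lists as the 13 were called by 5 splits (highest other 19), and 2 splits gave 2 or more genes in M2c-like cells (highest other 14). The split that set PBS replicate 1 with MATAC replicates 2 and 3 called 14 genes in M2c-like cells and 21 in LAM-like cells. The true grouping called 2 and 0. Whether chance or a structure among the libraries gave this was not tested.

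The first pattern weighed is the lower lipid-associated list in MATAC libraries, led by Fabp4, Fabp5 and Syngr1. Sequencing depth per cell is argued against, because with every cell thinned to 1 depth the list level stayed at -0.0935 (spread between libraries 0.0381). Whole cells of other types are argued against too, since among macrophage clusters alone the list level was -0.0722 (spread 0.0366). RNA of other cell types inside macrophage barcodes stays open, since leaving out clusters does not remove it. Neutrophil genes were higher inside M2c-like (median 0.41) and LAM-like cells (0.30). A smaller share of LAM-like and other rich clusters stays open: it would give -0.0375 of the measured -0.0800, and the remainder of -0.0425 had a spread of 0.0354 with groups that overlapped. An effect of MATAC inside the cells stays open as well.

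The second pattern is lower Fos in MATAC libraries. Different shares of the classes are argued against as the whole of it, because in each of the 4 classes tested the 95% interval of the Fos change lay below 0, with a highest upper bound of -0.0609. Depth is argued against, since in thinned cells Fos had -0.30 (adjusted p = 0.0330). The time and handling between culture and capture cannot be told apart from treatment: the whole immediate early and heat shock list had a median of -0.0572, the labels give no handling times, and a treatment effect stays open beside it.

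The third pattern lies in barcodes left out of the comparisons: the filters removed 16.3 ± 1.03% of PBS and 20.3 ± 1.85% of MATAC barcodes (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The number removed differed by 119 (spread 244), as a like number of poor droplets over fewer cells would give. Among barcodes of 2043 UMIs or more, 8859 ± 752 in PBS and 7286 ± 582 in MATAC libraries, the share over the mitochondrial limit was 2.11 ± 0.2497% and 3.30 ± 0.365%. This share was higher in each MATAC library than in each PBS library (1.19 points, spread 0.313, exact permutation p = 0.1). It rose by a larger factor than the number of such barcodes fell. For barcodes of this depth, that argues against a like number of poor droplets over fewer cells. For all removed barcodes a like number stays open. A lower depth of MATAC libraries was not seen, since the median per cell was higher by 635 UMIs (spread 606), but the groups overlapped and it is not excluded. More damaged cells after MATAC stay open as an untested biological explanation. RNA of the removed barcodes gave 0 of 8774 genes in edgeR, with 165 higher and 214 lower at unadjusted p under 0.05.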

How the results depend on the processing

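The shares and tests with a macrophage-only denominator, a depth minimum, library totals for the lists, a clustering without the 500 genes of smallest p, edgeR on classes and the interaction were chosen after seeing the data. Of 305 alternative fold changes of the 18 named genes with a fold, 12 passed the threshold, 3 changed sign and 290 were counted as unchanged in direction and side. The 290 include the DESeq2 values of Cxcr2, Coa4, Fosb and Nos2, to which DESeq2 gave no adjusted p-value, so their side is not known. Among the 290, Cxcr2 fell to 0.00275 among macrophage clusters, and Coa4 went from -0.23 to -0.12 in thinned cells. Those 12 came from DESeq2 (8), no low-count filter and thinned cells. The clustering without called genes was void, since 0 genes were called.

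For all cells the count of 0 genes became 126 with DESeq2, 2 without a low-count filter and 5 in thinned cells, and 0 to 7 when 1 library was left out (7 without PBS replicate 2). The 13 lists became 0 with an estimated correlation and 3 with fry, and 13 to 21 when 1 library was left out (21 without PBS replicate 2). Clusters called went from 0 to 0 to 1 (1 without PBS replicate 1) and classes called to 0 to 3 (3 without PBS replicate 2). Genes called in LAM-like cells became 11 with the replicate block, 21 with DESeq2, 76 without a low-count filter and 0 to 12 by library (12 without PBS replicate 1). In M2c-like cells the 2 became 1, 26 and 0 to 3. In cycling cells the 0 became 3, 141 and 0 to 7 (7 without PBS replicate 1), and in monocyte-like cells 6 with the replicate block, then 1, 39 and 0 to 3. The interaction gave 21 genes without a filter, all 6 among them, and 6 to 14 by library (14 without MATAC replicate 3), 4 shared each time. Without a filter more genes of few counts enter, and for the rest the cause was not tested.

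Changes of sign, when 1 library was left out, were seen for Lyz2 (-0.077 to 0.018), Mertk (-0.0058 to 0.078) and Nos2 (-0.870 to 0.513), none near a threshold. The M2c-like share differed by -3.17 points at resolution 0.4 (a single cluster led by Gm1673 and ribosomal protein genes), -0.289 with scaling within libraries and -0.159 to 2.67 by library. The monocyte-like share differed by 0.0559 points with doublets kept, 0.218 by marker score, 0.00991 without the 500 genes, 0.0399 among macrophage clusters and -0.120 to 0.150 by library. Shares of cells with a UMI changed sign for Arg1 (-0.00291 unthinned, -0.00623 to 0.0210 by library), Lyz2 (-0.704 to 0.186) and Nos2 (-0.00763 to 0.0123). The cause was not tested. Without 1 library the cycling share differed by 0.228 (without MATAC replicate 2) to 0.854 points (without PBS replicate 2). The LAM-like share was lower under every alternative run (-0.843 to -3.70 points), but 23.2% of cells have their 2 highest marker scores within 0.1, so class bounds are soft.

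Replicate numbers recur in both groups but did not pair the libraries (correlations of residuals of -0.018, 0.019 and -0.085 by number). With the replicate block edgeR called 0 genes in all cells (lowest adjusted p = 0.0520), 14 lists, 0 classes, 0 clusters, 2 genes in M2c-like and 0 in cycling cells. Depth limited Arg1 and Nos2, and single outlying libraries were not tested in groups of 3.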

Other observations

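The gene lists were read within each macrophage class after the results for all cells were seen, and the members named here were chosen after their values were seen. In monocyte-like cells the inflammatory (M1) list had a median log2 fold change of 0.24 (camera adjusted p = 2.7e-05; adjusted p = 0.499 with an estimated correlation). Adjusted over the list alone, the chemokine genes Ccl5 (0.86 ± 0.19, adjusted p = 0.00384) and Ccl4 (0.34 ± 0.12, 0.0499), Nfkbia, an inhibitor gene of NF-κB (0.31 ± 0.08, 0.00654), and Acod1, the itaconate enzyme gene (0.56 ± 0.19, 0.0475), were higher. In M2c-like cells the MHC class II list had a median of 0.17 (camera adjusted p = 2.3e-05; adjusted p = 0.695 with an estimated correlation), and adjusted over the list alone 5 of 8 members were higher and 0 lower, among them the master regulator gene Ciita (0.47 ± 0.11) and Cd74 (0.24 ± 0.06), at adjusted p = 0.00263 each. The same list had a median of 0.30 in monocyte-like cells (camera adjusted p = 0.00171; adjusted p = 0.499 with an estimated correlation) and of -0.05 in LAM-like cells, where it was not called (0.628). In the same M2c-like cells the neutrophil list, of another cell type, was higher as well (median 0.41, camera adjusted p = 0.00177; adjusted p = 0.695 with an estimated correlation). No difference between classes was tested for lists.

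In LAM-like cells the interferon response list had a median of 0.07 (camera adjusted p = 5.7e-06; adjusted p = 0.458 with an estimated correlation), and adjusted over the list alone 6 of 25 members were higher and 0 lower, with Ifit2 (0.27 ± 0.05, adjusted p = 0.00036) and Cmpk2 (0.29 ± 0.06, 0.00194) first. It was also called higher in monocyte-like (0.11, 3.8e-06; 0.580 with an estimated correlation) and cycling cells (0.09, 0.0395; 0.827 with an estimated correlation), while in M2c-like cells its median was -0.02, and it was not called (0.550). Lists of other cell types moved in LAM-like cells too: monocyte genes had a median of 0.45 (camera adjusted p = 0.00193; adjusted p = 0.458 with an estimated correlation) and neutrophil genes 0.30 with 8 of 8 members above 0 (0.00258; 0.458 with an estimated correlation). The lipid-associated list was called lower inside cycling cells (median -0.13, camera adjusted p = 9.8e-07; adjusted p = 0.699 with an estimated correlation), LAM-like cells (-0.08, 0.00016; 0.458 with an estimated correlation) and M2c-like cells (-0.07, 0.00207; 0.730 with an estimated correlation). It was not called in monocyte-like cells (0.02, 0.811). In cycling cells the monocyte list was called higher (0.21, camera adjusted p = 4.6e-06; adjusted p = 0.531 with an estimated correlation). Adjusted over the list alone, Fabp5 was lower in all 3 classes, while Ctsk, the cathepsin K gene, was higher in M2c-like cells (0.56 ± 0.15, adjusted p = 0.0128) and lower in cycling cells (-0.81 ± 0.24, 0.0227). Over all genes tested in its class, none of the members named here passed.

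Some clusters had a clear leading set of genes but no class name. An MHC class II cluster of 3707 cells held 7.10 ± 0.232% of PBS and 6.82 ± 0.388% of MATAC cells (SD, n = 3 each). A cluster of 1072 cells led by interferon genes held 1.87 ± 0.516% and 2.23 ± 0.438%, and 900 cells led by the granule genes Elane, Mpo and Prtn3 held 1.63 ± 0.156% and 1.74 ± 0.0762%. A cluster of 593 cells led by Ctla2a, Nrgn and the platelet gene Ppbp held 0.948 ± 0.137% and 1.31 ± 0.212% (log2 ratio 0.47 ± 0.17, adjusted p = 0.232 in edgeR). With all cells thinned to 2043 UMIs, edgeR called Ctla2a (0.86, adjusted p = 0.0006) and Nrgn (0.61, adjusted p = 0.0330) higher in MATAC libraries, but without thinning they had 0.61 (adjusted p = 0.374 in edgeR) and 0.28 (adjusted p = 0.738) and were not called. Within monocyte-like cells Ppbp had -2.35 ± 0.40 (adjusted p = 0.0599).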
